A study of Canis lupus familiaris with 9 samples.

How the data were processed

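Gene expression was measured in 9 samples of cultured dog cells (Canis lupus familiaris), each on its own Affymetrix array. There were 3 arrays each of skin fibroblasts (Fibroblast), of neural precursors grown from brain (Brain) and of neural precursors grown from skin (SKN). Fibroblasts were kept in medium with serum. SKN cells were kept without serum, with the growth factors EGF and FGF and the B-27 supplement, at first as floating spheres. The medium of the Brain cultures is not given in the labels used here, so medium and cell type cannot be told apart in any comparison. RNA was taken with Trizol from untreated cells and labelled as biotinylated cRNA. The labels do not say which dog gave which sample, nor whether the 3 samples of a group came from separate dogs or separate cultures, so each p measures only the spread between these samples.

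The values deposited by the authors form 1 table of 32205 probe sets in 9 columns, taken as log2 signals. The submitters' notes name MAS5, RMA and Partek, with no role, order or version. The log base is not written in the file. A log2 scale was inferred from the range of 0.561 to 13.47 and from array medians of 4.715 to 4.786, with quartiles nearly equal between arrays, as RMA leaves them. The values were used as deposited. The design called for leaving out the platform's control probe sets, but 0 names marked any, so all 32205 probe sets were tested and no filter on level was applied. For arrays, the number of samples limits the precision, and a low reading does not show that a transcript is absent.

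Of the probe sets, 16545 carried 1 gene symbol, 370 carried several and 15290 had no entry in the platform's table. The 15947 named genes were each represented by the probe set with the highest mean over the 9 arrays, and 516 of them had several probe sets. The dog reference table, of the build UU_Cfam_GSD_1.0, matched 15820 gene identifiers with 0 differing symbols. It served for names alone, and no coordinates were used.

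Comparisons used limma 3.58.1 in R 4.3.3. A linear model with 1 coefficient per group was fitted to all 9 arrays, with 6 residual degrees of freedom, and the variances were moderated with eBayes without trend (2.41 prior degrees of freedom). The 2-sided tests were adjusted by Benjamini-Hochberg over all probe sets in each of the 3 comparisons, and "called" means an adjusted p under 0.05. Differences are given in log2 units with the standard error (SE) of the fit, for 3 arrays against 3. A difference of 1 log2 unit is 2-fold. The table holds no detection calls, so a difference from a group with a low reading compares signals and is not a measured ratio of RNA. The genes, lists and alternatives below were fixed before the data were examined, except where stated. Named genes are, per comparison, the 10 with the largest positive and the 10 with the largest negative difference among called genes whose groups did not overlap, leaving out placeholder symbols. Any member of a fixed list, and the 5 leading genes of each class in the comparison of all 3 groups, was named as well.

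Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 72 tests (24 lists in 3 comparisons). An estimated correlation and fry were run beside it. The lists hold markers of neural stem and progenitor cells, neurons, astrocytes, the oligodendrocyte lineage, neural crest and Schwann cells, dermal papilla and skin-derived precursors, fibroblast matrix, keratinocytes and epithelium, melanocytes, microglia and other leukocytes, endothelium, pericytes and smooth muscle, adipocytes and skeletal muscle. Others hold contractile and serum response genes, cell cycle genes, cholesterol synthesis, hypoxia and glycolysis, interferon response, inflammatory mediators, matrix proteases and inhibitors, HOX genes, EGF and FGF feedback targets, and unfolded protein and amino acid stress. A list of housekeeping genes was counted but not tested, and a list of 8 sex-linked genes had 0 measured members. For each list, members were also adjusted over the list alone. Markers of a cell type are not specific to it in culture.

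Distances between arrays are root mean square differences in log2 units over all probe sets, with an exact 2-sided permutation test over the 20 assignments of the 6 Fibroblast and Brain arrays. Overlap of calls against Fibroblast was set beside that of independent lists, and the correlation, covariance and signs of the log2 differences beside 20 simulations of unchanged groups that share the same 3 Fibroblast arrays. The fit was tested on simulated data: per comparison, 63% to 65% of probe sets changed 2-fold and 90% or 91% of those changed 4-fold were recovered, with 6 to 10 false calls among 32205. The simulated noise was normal, independent between probe sets and drawn with the fit's own variances. These rates therefore follow from the model and do not gauge errors on the real arrays. Alternatives changed the variance moderation, the arrays in the fit, the normalization, the filter on dim probe sets, the array weights, the unit counted, the threshold and the list test, used the replicate number as a block, and left out each array in turn. A fit without Fibroblast 1 and Brain 3 was added after seeing the data.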

Results

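RNA levels were compared in 9 arrays of cultured dog cells: 3 of skin fibroblasts (Fibroblast), 3 of neural precursors from brain (Brain) and 3 of neural precursors from skin (SKN). The array medians lay between 4.715 and 4.786 log2 units, and values of arrays of the same group correlated across probe sets at 0.978 to 0.985. The first principal component held 56.66% of the variance and parted the Brain arrays from the rest, and the second, with 16.97%, parted SKN from Fibroblast. Within their groups 2 arrays, Fibroblast 1 and Brain 3, stood apart in gene groups typical of another culture. Their array weights over all probe sets, which are lower for less consistent arrays, were still the highest of their groups (1.36 and 1.49). Brain 1 had the lowest weight of the 9 arrays (0.565). Fibroblast 1 had a mean of 6.05 over the neural crest and Schwann cell list, against 5.49 and 5.37 in the other Fibroblast arrays, and CDH19, a cadherin of Schwann cell precursors, read 5.86 there against a mean of 2.48. Brain 3 had a mean of 7.20 over the fibroblast matrix list, against 6.22 and 6.38 in the other Brain arrays, and LUM, a collagen-binding proteoglycan, read 6.44 there against a mean of 2.60. Within SKN the cell cycle list averaged 7.16 in SKN 1, 4.51 in SKN 2 and 5.15 in SKN 3.

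**Figure D1:**
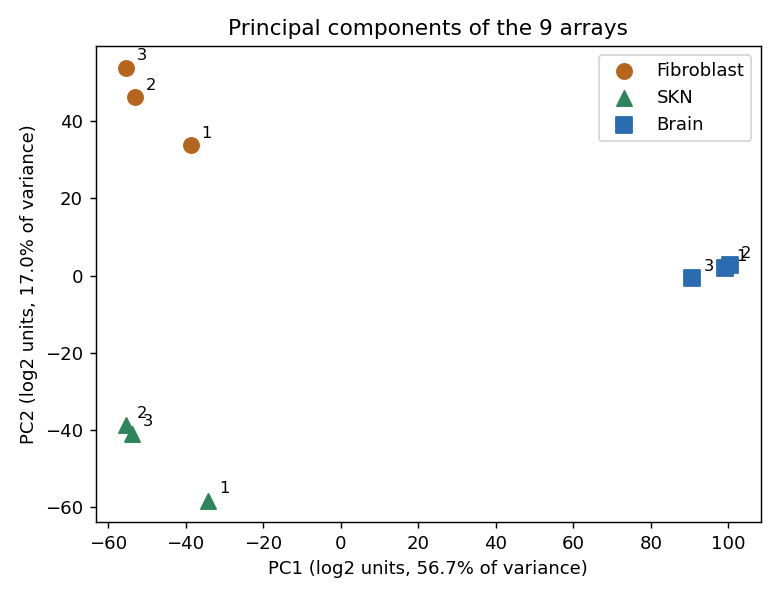
Principal components of the 9 arrays over all probe sets, with the first component (56.66% of the variance) on the x axis and the second (16.97%) on the y axis, both in log2 units, and each point an array marked by its group and number. The Brain arrays lie at 90.8 to 100.5 on the first component, and SKN at -58.3 to -38.8 and Fibroblast at 33.8 to 53.9 on the second.

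The comparison of SKN with Fibroblast asks how skin-derived precursors differ from fibroblasts of the same organ. SKN cells carried more CD34, a surface sialomucin of progenitor and stromal cells (log2 difference 5.83 ± 0.16 SE, n = 3 and 3), and more ABI3BP, an extracellular matrix protein (6.64 ± 0.39). The chemokine CXCL12 was higher by 6.20 ± 0.72 and the vasopressin receptor AVPR1A by 5.31 ± 0.48. SFRP2, a secreted modulator of Wnt signalling, was lower in SKN (-6.96 ± 0.43), and the growth factor FGF5 was lower as well (-4.73 ± 0.27). Other leading genes higher in SKN were F2RL2, a protease-activated receptor (6.46 ± 0.45), TMEFF2 (5.41 ± 0.45), the desmosomal plaque protein PPL (5.21 ± 0.18), the selenium carrier SELENOP (5.18 ± 0.60), the TGF-beta co-receptor TGFBR3 (5.12 ± 0.25) and the Wnt antagonist DKK2 (5.10 ± 0.73). Lower in SKN were NPR3, the clearance receptor of natriuretic peptides (-5.25 ± 0.53), AK5 (-5.04 ± 0.61), PGM5 (-4.92 ± 0.85), the retinol carrier RBP4 (-4.79 ± 0.28), the protease inhibitor TFPI2 (-4.59 ± 0.67), CCN3 (-4.57 ± 0.69), the hyaluronan receptor LYVE1 (-4.47 ± 0.94) and neuregulin, NRG1 (-4.26 ± 0.47). The call of LYVE1 (adjusted p 0.0427) ended without any of the 9 arrays but SKN 2 (0.054 to 0.1353), and with the replicate block (0.0829). That of PGM5 ended without Fibroblast 2 (0.0702), Fibroblast 3 (0.078) or SKN 3 (0.0557). The calls of DKK2 (0.0564), CCN3 (0.0638), TFPI2 (0.0575), LYVE1 (0.1373) and PGM5 (0.0885) were lost without variance moderation.

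Feedback targets of EGF and FGF signalling were higher in SKN than in Fibroblast. Of 18 measured members, 7 were higher, 0 lower and 11 not called, and adjusted over the list alone 14 were higher. SPRY1 rose by 3.09 ± 0.23, SPRY2 by 2.19 ± 0.26 and DUSP6 by 2.33 ± 0.27, all of them inhibitors that the pathway induces against itself. The list test gave an adjusted p of 5.2e-12 (adjusted p = 0.0566 with an estimated correlation). In cholesterol synthesis 6 of 16 members were higher, 0 lower and 10 not called, and adjusted over the list alone 14 were higher. SQLE, an oxygen-dependent step of the pathway, differed by 2.11 ± 0.33 and MSMO1 by 1.95 ± 0.31. The list test gave an adjusted p of 4.41e-12 (adjusted p = 0.377 with an estimated correlation). Per array the cholesterol synthesis list averaged 9.15 in SKN 1, 7.82 in SKN 2 and 8.23 in SKN 3, against 6.76 to 7.30 in Fibroblast. Of the 6 called cholesterol synthesis members, 0 kept the call through each removal of 1 array, MSMO1 and SQLE each losing it in 1 of the 9 removals, and 3 of the 7 called feedback targets (SPRY1, SPRY2, DUSP6) kept it.

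The fibroblast matrix list was abundant in SKN: LUM averaged 12.31 ± 0.04 (SD, n = 3) in SKN and 12.26 ± 0.09 in Fibroblast. Of its 25 measured members, 3 were higher in SKN, 2 lower and 20 not called, and adjusted over the list alone 6 were higher and 2 lower. FBLN1, a basement membrane glycoprotein, was higher by 3.15 ± 0.29 and DPT, a collagen-binding protein, by 2.79 ± 0.36, while the collagen COL5A1 was lower (-1.20 ± 0.14). The fibroblast matrix list as a whole was called higher at an adjusted p of 0.0463 (adjusted p = 0.722 with an estimated correlation). That call ended without any array but Fibroblast 2 and SKN 2 (0.0592 to 0.1135), with the replicate block (0.061), with the lower part of the probe sets by mean left out (0.101) and without Fibroblast 1 and Brain 3, chosen after seeing the data (0.131). Contractile and serum response genes lay lower in SKN as a list (adjusted p 0.00479, adjusted p = 0.554 with an estimated correlation), with 0 of 18 members higher, 2 lower (VCL and FLNA, which link actin to adhesions) and 16 not called. Adjusted over the list alone 5 of the contractile and serum response members were lower. The calls of VCL (-0.63 ± 0.14) and FLNA (-0.70 ± 0.12) ended in 7 and 4 of the 9 removals of 1 array, at adjusted p of up to 0.127 (without Fibroblast 3) and 0.0622 (without SKN 1).

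The calls among markers of neural cells stand beside 726 of 15947 genes called between SKN and Fibroblast. In the neural stem and progenitor list 0 of 19 members were higher and 1 lower, the homeobox gene DLX2 (-1.42 ± 0.22), with 18 not called and the same counts adjusted over the list alone. NES, an intermediate filament of precursors, averaged 6.67 ± 0.33 (SD, n = 3) in SKN and 6.65 ± 0.19 in Fibroblast, and SOX2 averaged 5.25 ± 0.34 and 5.17 ± 0.18. Among 25 neuronal genes, 2 were higher (STMN2, a regulator of microtubules in growing axons, by 3.91 ± 0.49, and NEFL by 0.62 ± 0.14) and 0 lower, and adjusted over the list alone 4 were higher and 2 lower. The call of NEFL ended in 7 of the 9 removals of 1 array (adjusted p up to 0.133, without Fibroblast 3). In the astrocyte list 1 of 17 was higher, ALDH1L1 (0.80 ± 0.17), and 0 lower, with 2 higher adjusted over the list alone, and its call ended in 7 removals (up to 0.115, without Fibroblast 2). The oligodendrocyte lineage list had 0 of 11 called and 1 higher adjusted over the list alone. The neural crest and Schwann cell list had 0 of 16 higher and 1 lower, TFAP2A (-1.56 ± 0.32), a crest transcription factor, and 3 higher and 1 lower adjusted over the list alone. The call of TFAP2A ended in 8 removals (up to 0.117, without SKN 3). None of these 5 lists was called by camera, with adjusted p of 0.425, 0.408, 0.397, 0.61 and 0.998 in the order given. Fry called none for a shift in 1 direction. For change in either direction fry called all 5 (adjusted p 1.9e-04, 2.5e-05, 3.3e-04, 0.0049 and 1.3e-04), as it did 65 of the 72 list tests. At an unadjusted p under 0.05 the lists had 4, 8, 4, 1 and 5 members. Median and mean differed in sign for the neuronal (-0.07 and 0.24), astrocyte (-0.03 and 0.35) and crest (-0.10 and 0.02) lists. Where median and mean differ in sign, here and in the other comparisons, camera took the sign of the mean unless stated.

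Other lists that camera called between SKN and Fibroblast were the matrix proteases and inhibitors, higher, and the unfolded protein and amino acid stress genes, lower. Among 15 proteases and inhibitors TIMP1, an inhibitor of metalloproteinases, was called higher (1.37 ± 0.20) and 0 lower, and 3 were higher adjusted over the list alone (list adjusted p 0.0343, adjusted p = 0.442 with an estimated correlation). This call of the matrix proteases and inhibitors ended without Fibroblast 1 (0.157) or SKN 2 (0.131), with the lower part of the probe sets by mean left out (0.126) and without Fibroblast 1 and Brain 3, chosen after seeing the data (0.155). Among 15 stress genes 0 were higher and 1 lower, VLDLR (-1.40 ± 0.30, lost in 7 removals, adjusted p up to 0.151, without Fibroblast 3), and 4 were lower adjusted over the list alone (list adjusted p 0.0385, adjusted p = 0.554 with an estimated correlation). The call of the unfolded protein and amino acid stress list ended without Fibroblast 1 (0.0849), Fibroblast 2 (0.098) or SKN 2 (0.109), and without Fibroblast 1 and Brain 3 together (0.0732). Dermal papilla and skin-derived precursor genes had 2 of 17 higher and 1 lower, SFRP2, with 4 higher and 1 lower adjusted over the list alone (list adjusted p 0.154, 0.0302 without Fibroblast 3). The HOX list had 1 of 25 higher, HOXD8 (0.91 ± 0.11), and 0 lower, with the same counts adjusted over the list alone (list adjusted p 0.81). Inflammatory mediators had 2 of 17 higher, CXCL12 among them, and 1 lower, the adhesion molecule VCAM1 (-3.09 ± 0.49), with the same counts adjusted over the list alone (list adjusted p 0.401, median -0.0044, mean 0.42 and camera upward).

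The cell cycle list had 0 of 24 members called by limma between SKN and Fibroblast, over all probe sets and adjusted over the list alone, with 2 at an unadjusted p under 0.05 and a list adjusted p of 0.0872. That cell cycle test passed, higher in SKN, without SKN 3 (0.0185) and with the replicate block (0.0089). It also passed without Fibroblast 1 (0.00233) and without SKN 2 (2.0e-04), and without Fibroblast 1 and Brain 3, chosen after seeing the data (0.00355). Without SKN 1 it turned lower (0.225). Hypoxia and glycolysis genes had 1 of 20 higher and 2 lower, with 2 higher and 6 lower adjusted over the list alone (list adjusted p 0.154, 0.0435 without Fibroblast 1 and 0.0301 without Fibroblast 1 and Brain 3). Interferon response genes had 0 of 15 higher and 1 lower, with the same counts adjusted over the list alone (list adjusted p 0.152, 0.011 without Fibroblast 2). The interferon response list averaged 4.85 in Fibroblast 1 against 3.96 and 4.04 in the other Fibroblast arrays. Camera called no list among markers of other cell types. Endothelial genes had 1 of 14 higher and 2 lower, among them the transcription factor ERG (-1.32 ± 0.20), with 2 higher and 3 lower adjusted over the list alone (list adjusted p 0.868). Melanocyte genes had 1 of 12 higher and 0 lower on both adjustments (over all probe sets and adjusted over the list alone, list adjusted p 0.859). Pericyte and smooth muscle (10 measured, 2 higher and 2 lower adjusted over the list alone, list adjusted p 0.81) and adipocyte genes (11 measured, 2 higher adjusted over the list alone, 0.905, median -0.11, mean 0.003 and camera upward) had 0 called by limma over all probe sets, with 4 and 2 at an unadjusted p under 0.05. Keratinocyte and epithelial (19 measured, list adjusted p 0.589), microglia and other leukocyte (16, 0.802) and skeletal muscle genes (11, 0.401) had 0 called on both adjustments, with 2, 3 and 1 at an unadjusted p under 0.05.

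Over all probe sets limma called 1076 of 32205 between SKN and Fibroblast, 623 higher in SKN and 453 lower, and 682 of them differed at least 2-fold (429 higher, 253 lower). By gene, 391 were higher and 335 lower. At an unadjusted p under 0.05 there were 5395 probe sets. The count was 670 without Fibroblast 2, 513 without Fibroblast 3, 593 without SKN 1 and 624 without SKN 3, and the 2-fold count was 410 without Fibroblast 3. Without Fibroblast 1 and Brain 3, an alternative chosen after seeing the data, it was 516, with the replicate block 835 and without variance moderation 488. Of the 40 called list members outside the leading genes, 30 lost their call without moderation.

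**Figure D2:**
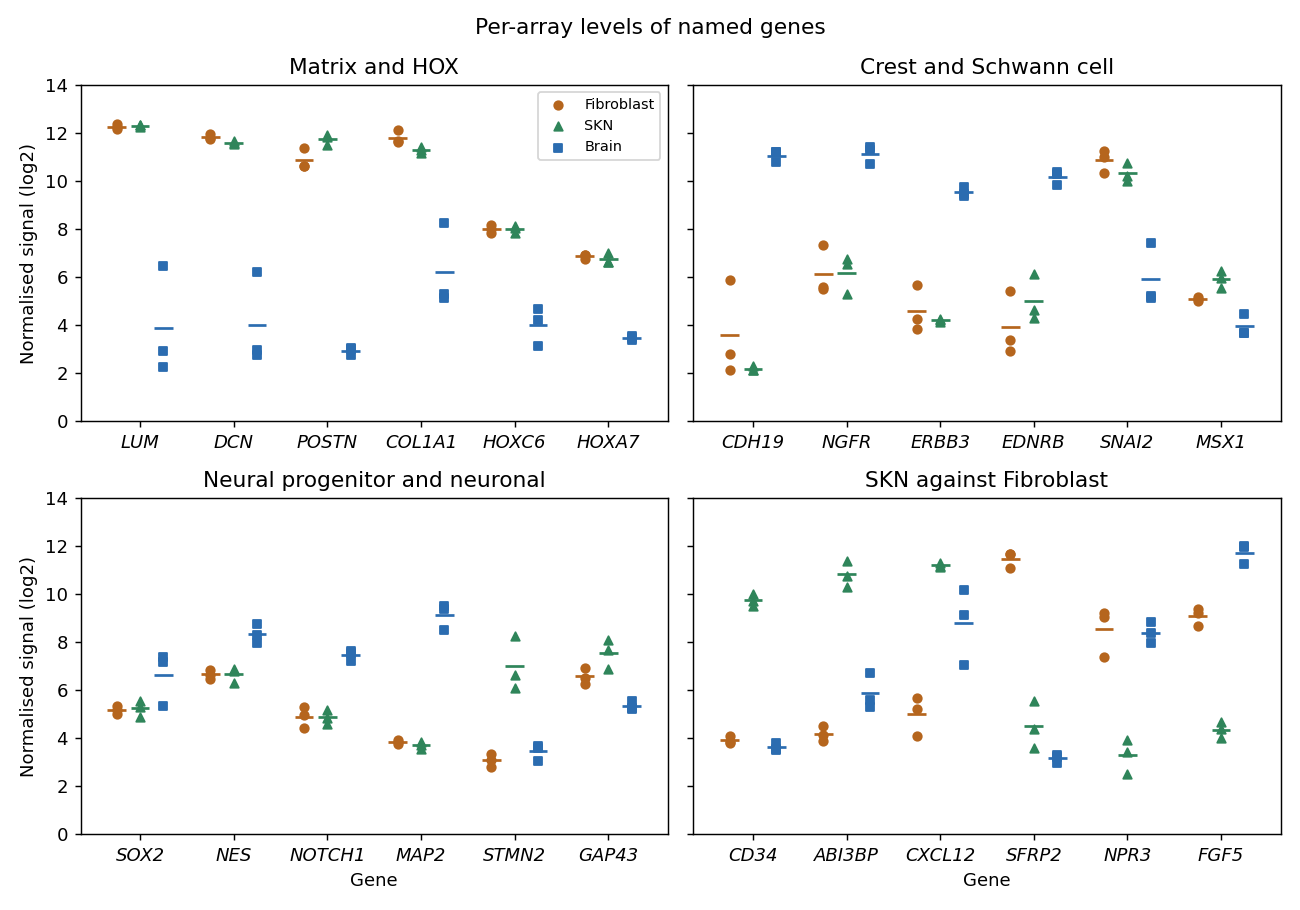
Log2 signal (y axis) of selected genes (x axis) on each of the 9 arrays, with points for arrays coloured by group and bars for group means, in panels for stromal and HOX genes, neural crest genes, neural genes and genes that part SKN from Fibroblast. LUM averages 12.31 in SKN and 12.26 in Fibroblast, with 6.44 on Brain 3, and CDH19 averages 11.06 in Brain, with 5.86 on Fibroblast 1.

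The comparison of SKN with Brain asks how precursors grown from skin differ from those grown from brain. POSTN, a matrix protein of periosteum and skin, was higher (8.82 ± 0.22 SE, n = 3 and 3), the microfibril protein MFAP5 was higher by 8.70 ± 0.20, LUM by 8.43 ± 0.90 and DCN, a collagen-binding proteoglycan, by 7.61 ± 0.78. CDH19 was lower in SKN (-8.87 ± 0.80), as were UGT8, which makes the galactolipids of myelin (-7.32 ± 0.69), and GFRA1, the receptor of the neurotrophic factor GDNF (-7.36 ± 0.92). The remaining leading genes higher in SKN were the surface protease FAP (7.05 ± 0.18), VNN1 (7.03 ± 1.16), ASPN (6.86 ± 0.23), DPT (6.63 ± 0.36), podoplanin, PDPN (6.58 ± 0.30), and AVPR1A (6.21 ± 0.48). Those lower in SKN were FGF5 (-7.37 ± 0.27), the alarmin cytokine IL33 (-6.84 ± 1.01), the collagen-modifying enzyme P3H2 (-6.75 ± 0.49), the synaptic adhesion molecule NLGN4X (-6.63 ± 0.39), ENPP6, a phosphodiesterase of oligodendrocytes (-6.51 ± 0.43), ADAMTS20 (-6.44 ± 0.20) and the membrane protein GPM6B (-6.35 ± 0.55).

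All 20 called members of the fibroblast matrix list were higher in SKN than in Brain, 0 were lower and 5 of 25 were not called, with the same counts adjusted over the list alone. COL1A1 was higher by 5.08 ± 0.72 and the procollagen enhancer PCOLCE by 5.06 ± 0.24 (list adjusted p 1.87e-14, adjusted p = 0.214 with an estimated correlation). Brain 3 had a fibroblast matrix mean of 7.20 and a contractile mean of 8.20, against 6.38 or less and 6.76 or less in the other Brain arrays. Of 18 contractile and serum response genes 10 were higher in SKN, 0 lower and 8 not called, with 13 higher adjusted over the list alone. Tropomyosin TPM2 was higher by 5.28 ± 1.03 and caldesmon, CALD1, by 2.71 ± 0.36 (list adjusted p 2.42e-04, adjusted p = 0.387 with an estimated correlation). HOX genes, which record position along the body axis, were higher in SKN for 15 of 25 members and lower for 0, with 10 not called and 16 higher adjusted over the list alone. HOXC6 was higher by 3.99 ± 0.34, HOXA7 by 3.29 ± 0.13 and HOXD8 by 3.27 ± 0.11 (list adjusted p 1.71e-09, adjusted p = 0.0566 with an estimated correlation). Unfolded protein and amino acid stress genes had 10 of 15 higher, 1 lower and 4 not called, and 13 higher and 1 lower adjusted over the list alone, with the cystine carrier SLC7A11 at 4.74 ± 0.28 (list adjusted p 1.16e-06, adjusted p = 0.214 with an estimated correlation). Through each removal of 1 array the call was kept by 20 of 20 matrix, 4 of 10 contractile, 11 of 15 HOX and 10 of 11 stress genes, TPM2, CALD1, HOXC6, HOXA7, HOXD8 and SLC7A11 among those kept.

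Neural crest and Schwann cell genes were lower in SKN than in Brain for 9 of 16 members and higher for 3, with 4 not called and the same counts adjusted over the list alone. NGFR, the low-affinity neurotrophin receptor, was lower in SKN (-4.94 ± 0.54), as were the neuregulin receptor ERBB3 (-5.33 ± 0.40) and the endothelin receptor EDNRB (-5.15 ± 0.67), while SNAI2, a transcription factor of crest and mesenchyme, was higher (4.40 ± 0.57). The neural crest and Schwann cell list test gave an adjusted p of 0.00984 (adjusted p = 0.263 with an estimated correlation). In the neural stem and progenitor list 1 of 19 was higher in SKN, the homeobox gene EMX2 (1.99 ± 0.23), and 5 lower, among them NES (-1.67 ± 0.23) and NOTCH1 (-2.57 ± 0.24), with 2 higher and 6 lower adjusted over the list alone (list adjusted p 0.397). Neuronal genes went both ways, with 5 of 25 higher and 5 lower on both adjustments (over all probe sets and adjusted over the list alone, list adjusted p 0.81). STMN2 was higher by 3.54 ± 0.49 and INA, a neuronal intermediate filament, by 2.21 ± 0.29, while the dendritic protein MAP2 (-5.42 ± 0.24) and the adhesion molecule L1CAM (-5.14 ± 0.34) were lower. The neuronal median was 0.05 and its mean -0.40. Astrocyte genes had 5 of 17 higher and 4 lower, with 5 and 5 adjusted over the list alone (list adjusted p 0.868), the chaperone CLU at 4.73 ± 0.49 and the adhesion protein HEPACAM at -3.67 ± 0.20. In the oligodendrocyte lineage list 1 of 11 was higher, PDGFRA (4.64 ± 0.43), also a receptor of connective tissue cells, and 4 lower, among them the myelin enzyme CNP (-2.74 ± 0.20), with 2 higher and 4 lower adjusted over the list alone (list adjusted p 0.226). Each call named here stayed when any 1 array was left out.

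Cell cycle genes were lower in SKN than in Brain for 11 of 24 members and higher for 0, with 13 not called and 23 lower adjusted over the list alone. The helicase subunit MCM7 was lower (-1.21 ± 0.25). The cell cycle list test gave an adjusted p of 3.01e-07 (adjusted p = 0.631 with an estimated correlation), and only MCM7 of the 11 calls stayed through each removal of 1 array. The cell cycle list averaged 7.16 in SKN 1 but 4.51 and 5.15 in SKN 2 and SKN 3, against 7.33 to 8.46 in Brain. Dermal papilla and skin-derived precursor genes were higher in SKN for 6 of 17 members and lower for 1, with 10 not called and 8 higher and 1 lower adjusted over the list alone. The growth factor FGF7 was higher by 5.82 ± 0.48 and the T-box factor TBX18 by 5.10 ± 0.43 (list adjusted p 0.00902, adjusted p = 0.369 with an estimated correlation), and 3 of the 7 calls (FGF7, TBX18 and BMP4 at 3.72 ± 0.51) stayed through each removal. Inflammatory mediators had 6 of 17 higher and 1 lower, IL33, with 7 and 1 adjusted over the list alone (list adjusted p 0.0494, adjusted p = 0.554 with an estimated correlation). The chemokine CCL2 was higher by 2.95 ± 0.48 and ICAM1 by 2.82 ± 0.20. The call of the inflammatory mediators ended without Fibroblast 2 (0.0602), Brain 2 (0.0737), SKN 1 (0.112) or SKN 2 (0.0718).

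Camera called no other list between SKN and Brain, and the list adjusted p given here are those of camera. Fry called 4 of the lists below higher in SKN. They were pericyte and smooth muscle (adjusted p 9.15e-05), endothelial (0.0091), EGF and FGF feedback targets (0.0095) and adipocyte (0.0144). Of the neural lists above that camera had not called, fry called oligodendrocyte lineage (0.0052) and neuronal genes (0.0234), both lower in SKN. EGF and FGF feedback targets had 6 of 18 higher and 2 lower, with 7 and 2 adjusted over the list alone (list adjusted p 0.101, 0.0353 without SKN 3), and ETV4, a transcription factor of the pathway, was higher by 1.86 ± 0.32. Cholesterol synthesis genes had 0 of 16 called by limma on both adjustments (over all probe sets and adjusted over the list alone), with 0 at an unadjusted p under 0.05 (list adjusted p 0.802). Hypoxia and glycolysis genes had 4 of 20 higher and 4 lower, with the same counts adjusted over the list alone (list adjusted p 0.81), the prolyl hydroxylase EGLN3 at 3.17 ± 0.21 and the glycolytic regulator PFKFB3 at -1.93 ± 0.40. Matrix proteases and inhibitors had 2 of 15 higher and 2 lower, with 3 and 2 adjusted over the list alone (0.397), and TIMP1 was higher by 2.22 ± 0.20. Interferon response genes had 2 of 15 higher, among them OAS2 (4.27 ± 0.36), and 0 lower, with 3 higher adjusted over the list alone (0.71). Endothelial genes had 5 of 14 higher and 2 lower, with 6 and 2 adjusted over the list alone (0.126, 0.0443 without Brain 3 and 0.0391 without Fibroblast 1 and Brain 3, chosen after seeing the data), the sialomucin EMCN at 3.26 ± 0.59. Pericyte and smooth muscle genes had 4 of 10 higher and 1 lower, with 5 and 1 adjusted over the list alone (0.0872, 0.0385 without Brain 3, 0.0432 without SKN 2 and 0.0335 without Fibroblast 1 and Brain 3), the peptidase ANPEP at 5.31 ± 0.16 and MCAM at -4.62 ± 0.42. Adipocyte genes had 2 of 11 higher and 0 lower (0.43), and melanocyte genes 2 of 12 higher and 1 lower (0.81), with the same counts adjusted over the list alone. Microglia and other leukocyte genes had 1 of 16 higher (0.609) and keratinocyte and epithelial genes 0 of 19 higher and 1 lower, the integrin ITGB4 (-5.25 ± 0.38, list adjusted p 0.81), each with the same counts adjusted over the list alone. Keratinocyte and epithelial genes had a median of 0.02 and a mean of -0.18. Skeletal muscle genes had 0 of 11 called by limma on both adjustments, with 0 at an unadjusted p under 0.05 (0.413).

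In all 5271 probe sets were called between SKN and Brain, 2459 higher in SKN and 2812 lower, and 2790 of them at least 2-fold (1342 higher, 1448 lower). By gene, 1744 were higher and 1864 lower. At an unadjusted p under 0.05 there were 9103 probe sets. The count was 4946 with the replicate block and 3366 without Fibroblast 1 and Brain 3, an alternative chosen after seeing the data.

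The comparison of Brain with Fibroblast sets the 2 reference cultures against each other. Brain cells carried more ENPP2, the enzyme autotaxin that makes lysophosphatidic acid (7.98 ± 0.27 SE, n = 3 and 3), and more CDH19 (7.45 ± 0.80), GFRA1 (6.73 ± 0.92) and UGT8 (6.64 ± 0.69). They carried less LUM (-8.38 ± 0.90), SFRP2 (-8.31 ± 0.43), MFAP5 (-8.26 ± 0.20) and ASPN (-8.11 ± 0.23), all of them secreted proteins. Also higher in Brain were IL33 (6.56 ± 1.01), the neural adhesion molecule CHL1 (6.43 ± 0.94), the retinoid receptor RXRG (6.37 ± 0.33), EDNRB (6.26 ± 0.67), ADAMTS20 (6.24 ± 0.20) and NLGN4X (6.14 ± 0.39). Also lower were POSTN (-7.94 ± 0.22), DCN (-7.84 ± 0.78), TFPI2 (-7.63 ± 0.67), the tetraspanin-like TM4SF1 (-6.89 ± 0.77), FAP (-6.83 ± 0.18) and SVEP1 (-6.61 ± 0.40). Each of these 20 genes stayed called when any 1 array was left out. CDH19 and CHL1 read 5.86 and 7.04 on Fibroblast 1, against means of 2.48 and 3.18 on the other Fibroblast arrays.

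Cell cycle genes were higher in Brain than in Fibroblast for 21 of 24 members and lower for 0, with 3 not called and 24 higher adjusted over the list alone. The helicase subunits MCM2 (2.49 ± 0.47) and MCM4 (2.27 ± 0.39) and the transcription factor E2F1 (1.90 ± 0.27) were higher, and with MCM7 they were the 4 of the 21 whose call stayed through each removal of 1 array. The cell cycle list test gave an adjusted p of 5.94e-09 (adjusted p = 0.569 with an estimated correlation). Fibroblast 1 averaged 6.07 over the cell cycle list, against 4.96 and 4.78 in the other Fibroblast arrays. Neural crest and Schwann cell genes were higher in Brain for 9 of 16 members and lower for 4, with 3 not called and the same counts adjusted over the list alone, NGFR by 4.99 ± 0.54 and ERBB3 by 4.94 ± 0.40 (list adjusted p 0.00983, adjusted p = 0.263 with an estimated correlation). SNAI2 was lower (-4.94 ± 0.57). On Fibroblast 1 NGFR read 7.32, against a mean of 5.55 on the other Fibroblast arrays. Cholesterol synthesis genes were higher in Brain for 8 of 16 members and lower for 0, with 8 not called and 14 higher adjusted over the list alone, SQLE by 2.41 ± 0.33 and HMGCS1, the synthase that starts the pathway, by 2.10 ± 0.42 (list adjusted p 5.87e-06, adjusted p = 0.569 with an estimated correlation). EGF and FGF feedback targets were higher for 5 of 18 members and lower for 1, with 12 not called and 6 and 1 adjusted over the list alone, SPRY1 by 3.32 ± 0.23 and SPRY2 by 3.09 ± 0.26 (list adjusted p 0.0223, adjusted p = 0.387 with an estimated correlation). This call of the EGF and FGF feedback targets ended with the lower part of the probe sets by mean left out (0.0923).

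Fibroblast matrix genes were lower in Brain than in Fibroblast for 18 of 25 members and higher for 1, FBLN1 (1.11 ± 0.29, lost in 4 of the 9 removals of 1 array, adjusted p up to 0.087 without Fibroblast 3), with 6 not called and 19 lower and 2 higher adjusted over the list alone. COL1A1 was lower (-5.58 ± 0.72), as was FBLN2 (-5.41 ± 0.21) (list adjusted p 5.31e-10, adjusted p = 0.272 with an estimated correlation). Contractile and serum response genes were lower for 14 of 18 members and higher for 0, with 4 not called and 16 lower adjusted over the list alone, smooth muscle calponin, CNN1, at -6.49 ± 0.88 and the growth factor CCN2 at -5.16 ± 1.09 (list adjusted p 1.0e-06, adjusted p = 0.276 with an estimated correlation). Brain 3 read 9.59 for the smooth muscle actin ACTA2, against a mean of 4.02 on the other Brain arrays. HOX genes were lower for 17 of 25 members and higher for 0, with 8 not called and 21 lower adjusted over the list alone, HOXC6 at -3.98 ± 0.34 and HOXA7 at -3.40 ± 0.13 (list adjusted p 2.7e-09, adjusted p = 0.0566 with an estimated correlation). Unfolded protein and amino acid stress genes were lower for 13 of 15 members and higher for 0, with 2 not called and 14 lower adjusted over the list alone, SLC7A11 at -4.66 ± 0.28 and the glutathione-degrading enzyme CHAC1 at -3.31 ± 0.19 (list adjusted p 4.89e-08, adjusted p = 0.202 with an estimated correlation). Calls that stayed through each removal of 1 array numbered 16 of 19, 12 of 14, 14 of 17 and 12 of 13 in these 4 lists.

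The remaining lists were not called by camera between Brain and Fibroblast, and the list adjusted p given here are those of camera. Fry called neuronal (adjusted p 0.0076) and oligodendrocyte lineage genes (0.0116) higher in Brain. It called lower in Brain the pericyte and smooth muscle (5.19e-05), dermal papilla (0.0039), endothelial (0.0041), adipocyte (0.0128) and inflammatory mediator (0.0263) lists. Neural stem and progenitor genes had 3 of 19 higher, among them NOTCH1 (2.56 ± 0.24) and NES (1.68 ± 0.23), and 1 lower, EMX2 (-2.11 ± 0.23), with the same counts adjusted over the list alone (list adjusted p 0.845, median -0.07 and mean 0.24). Neuronal genes had 5 of 25 higher, among them MAP2 (5.29 ± 0.24) and STMN4 (3.07 ± 0.18), and 2 lower, with the same counts adjusted over the list alone (0.401). Astrocyte genes had 3 of 17 higher, among them the water channel AQP4 (2.33 ± 0.31), and 3 lower, with the same counts adjusted over the list alone (0.81, median -0.07 and mean 0.12). Oligodendrocyte lineage genes had 4 of 11 higher, among them the myelin glycoprotein MOG (2.44 ± 0.23) and SOX10 (1.53 ± 0.19), and 1 lower, PDGFRA (-2.91 ± 0.43), with 4 and 3 adjusted over the list alone (0.513, median -0.14 and mean 0.83). Hypoxia and glycolysis genes had 2 of 20 higher and 7 lower, with 2 and 8 adjusted over the list alone (0.233, 0.0221 without Fibroblast 1 and Brain 3, chosen after seeing the data), and VEGFA was lower (-1.21 ± 0.25). Interferon response genes had 0 of 15 higher and 4 lower, with the same counts adjusted over the list alone (0.152, 0.0333 without Fibroblast 2), OAS2 at -4.14 ± 0.36. Inflammatory mediators had 2 of 17 higher and 5 lower, with 3 and 5 adjusted over the list alone (0.373). Matrix proteases and inhibitors had 4 of 15 higher and 2 lower, with 4 and 3 adjusted over the list alone (0.868, median -0.21 and mean 0.30). Dermal papilla and skin-derived precursor genes had 0 of 17 higher and 5 lower, with 1 and 5 adjusted over the list alone (0.222). Pericyte and smooth muscle genes had 1 of 10 higher and 3 lower, with 1 and 5 (0.126). Endothelial genes had 0 of 14 higher and 2 lower, with the same counts (0.24), and adipocyte genes 0 of 11 higher and 2 lower, with the same counts (0.408). Keratinocyte and epithelial genes had 1 of 19 higher, ITGB4 (4.61 ± 0.38), and 1 lower, with 1 and 0 adjusted over the list alone (0.949, median -0.07, mean 0.14 and camera downward). Melanocyte genes had 1 of 12 higher and 1 lower, with 2 and 1 adjusted over the list alone (0.81), and microglia and other leukocyte genes 0 of 16 higher and 1 lower, with 0 and 0 adjusted over the list alone (0.413). Skeletal muscle genes had 0 of 11 called by limma on both adjustments, with 1 at an unadjusted p under 0.05 (0.868).

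In all 6638 probe sets were called between Brain and Fibroblast, 3622 higher in Brain and 3016 lower, and 3202 of them at least 2-fold (1858 higher, 1344 lower). By gene, 2207 were higher and 2101 lower. At an unadjusted p under 0.05 there were 10647 probe sets. The count was 6026 with the replicate block and 3657 without Fibroblast 1 and Brain 3, an alternative chosen after seeing the data. Of the 72 list tests in the 3 comparisons camera called 22 at the preset correlation and 0 with an estimated correlation (median correlation 0.068). The estimated correlation was 0.895 for cell cycle, 0.789 for cholesterol synthesis and 0.2645 for fibroblast matrix. These lie far above the preset 0.01, so the small camera p of these lists rest on that setting. Fry called 32 of the 72 tests for a shift in 1 direction and 65 for change in either direction. Fry, which does not set a list against other genes, gave adjusted p of 0.298, 0.064 and 0.066 for the fibroblast matrix, contractile and protease lists between SKN and Fibroblast, which camera had called. The other way round, fry called lists that camera had not, named above in the comparisons of SKN and of Fibroblast with Brain.

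**Figure D3:**
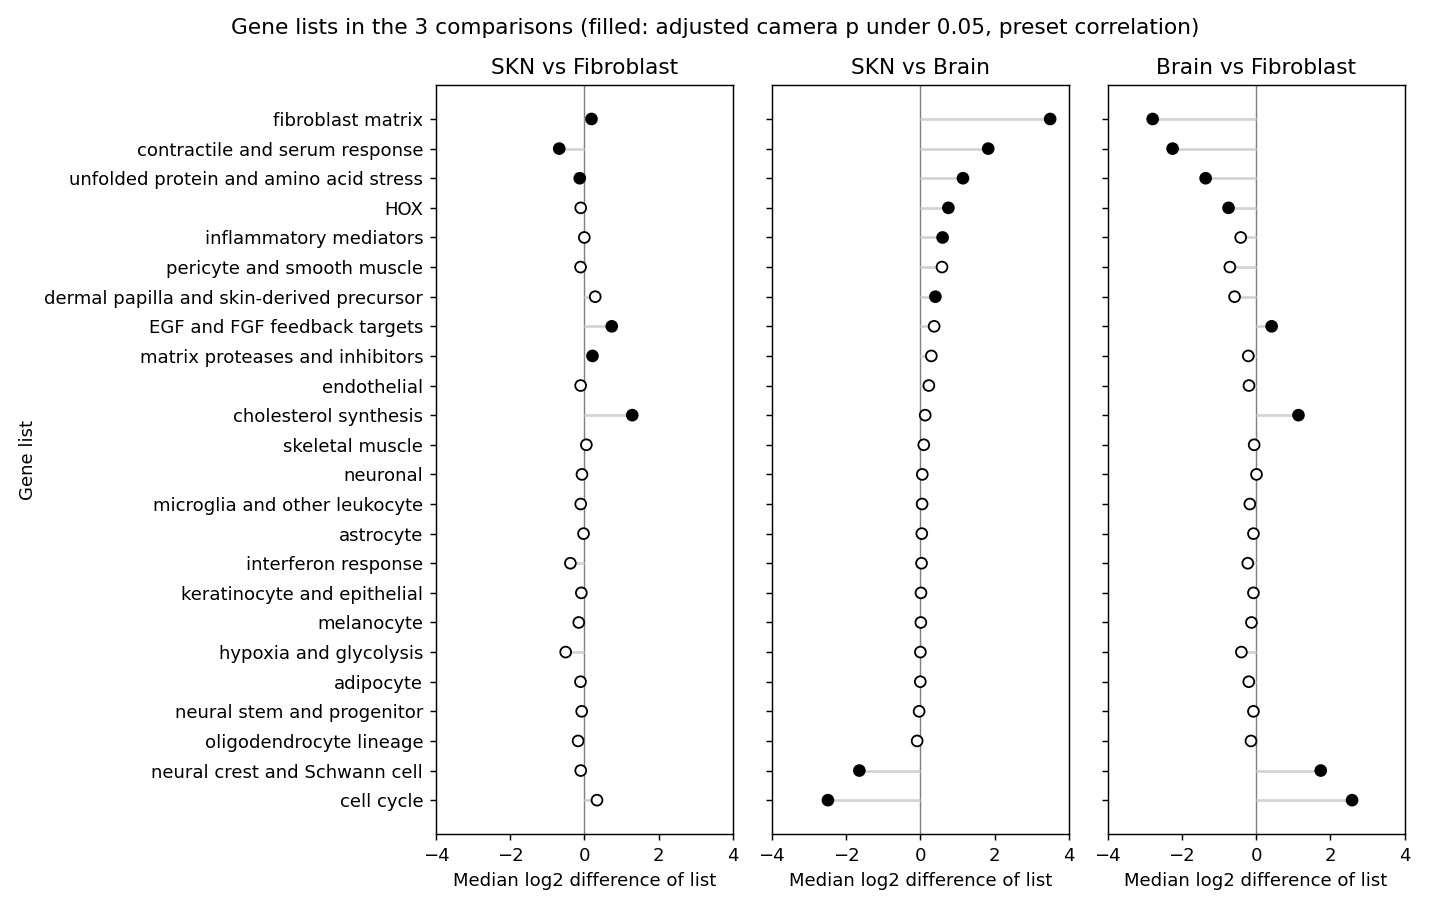
Median log2 difference of the members (x axis) of each of the 24 gene lists (y axis) in the 3 comparisons, with filled points for lists with an adjusted camera p under 0.05 at the preset correlation. Fibroblast matrix stands at 3.50 for SKN against Brain and -2.78 for Brain against Fibroblast, and cholesterol synthesis at 1.29 for SKN against Fibroblast and 1.14 for Brain against Fibroblast.

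The position of SKN relative to both other cultures was described by genes called in more than 1 comparison. Of 15947 genes, 246 were higher in SKN than in both others, led by CD34 (5.83 ± 0.16 over Fibroblast and 6.10 ± 0.16 over Brain), AVPR1A, PPL, ABI3BP and ADCYAP1R1, a neuropeptide receptor (4.82 and 5.10, each ± 0.22). In SKN 91 genes were lower than in both, led by NPR3, FGF5, LIN7A (-3.76 and -4.89, each ± 0.52), the creatine synthesis enzyme GATM (-3.13 and -4.64, each ± 0.57) and the phosphodiesterase PDE5A (-2.84 and -3.45, each ± 0.51). SKN and Fibroblast stood together above Brain, with SKN and Fibroblast not called apart, in 1058 genes led by LUM, MFAP5, POSTN, DCN and FAP. They stood together below Brain in 1406 genes led by CDH19, GFRA1, UGT8, IL33 and ADAMTS20. SKN and Brain stood together above Fibroblast in 90 genes led by SELENOP, TGFBR3, the lactate and pyruvate carrier SLC16A7 (4.36 over Fibroblast in SKN and 4.34 in Brain, each ± 0.25), the monoamine oxidase MAOA (4.09 and 4.95, each ± 0.81) and CXCL12. They stood together below Fibroblast in 176 genes led by SFRP2, CCN3, LYVE1, AK5 and NRG1. Not being called apart does not show equal levels.

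Calls of SKN against Fibroblast were lost for GATM without SKN 1 (0.079), SKN 2 (0.062) or SKN 3 (0.0693), and for PDE5A without Fibroblast 1 (0.066), Fibroblast 3 (0.0586), SKN 1 (0.078), SKN 2 (0.0575) or SKN 3 (0.0598). That of MAOA was lost without any array but Fibroblast 1 and Fibroblast 2 (0.0515 to 0.105), and that of LYVE1 without any but SKN 2 (0.054 to 0.1353). The 246 genes higher than in both became 143 without Fibroblast 2, 126 without Fibroblast 3 and 159 without SKN 3. The 91 lower than in both became 54 without Fibroblast 2, 44 without Fibroblast 3, 53 without SKN 1, 60 without SKN 2 and 41 without SKN 3. The 90 above Fibroblast in SKN and Brain became 58 without Fibroblast 1, 49 without Fibroblast 2, 41 without Fibroblast 3, 41 without SKN 1 and 48 without SKN 3. The 176 below became 79 without Fibroblast 3, 79 without SKN 1 and 106 without SKN 3. Without Fibroblast 1 and Brain 3 together, an alternative chosen after seeing the data, the 246, 91, 90, 176, 1058 and 1406 became 112, 41, 35, 87, 663 and 782.

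Against the same 3 Fibroblast arrays, SKN and Brain shared 198 probe sets called higher and 323 called lower, SFRP2 and CXCL12 among the genes shared, and 123 went opposite ways. Independent lists of the same sizes would share 70.1 and 42.4, values that leave out the shared Fibroblast arrays. No such value was computed for the 123, so that count cannot be read as few or many. Across probe sets, which are not independent replicates, the log2 differences of SKN and of Brain from Fibroblast correlated at 0.302. Simulation of unchanged groups gave 0.499, a value that the shared control fixes by construction. Differences in only 1 of the 2 cultures lower the correlation, so 0.302 does not tell how alike SKN and Brain are. The covariance of the log2 differences was 0.130 against a simulated 0.0285. Their signs matched in 67.3% of probe sets against 66.7% in simulation, likewise fixed by construction. The 3 Fibroblast arrays are too few to divide between the comparisons. The 198 became 105 without Fibroblast 2, 84 without Fibroblast 3, 101 without SKN 1 and 118 without SKN 3. The 323 became 146 without Fibroblast 3, 148 without SKN 1 and 174 without SKN 3. The 123 became 80 without Fibroblast 2, 66 without Fibroblast 3 and 78 without SKN 3. Without Fibroblast 1 and Brain 3, an alternative chosen after seeing the data, they were 85, 159 and 62.

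SKN arrays lay nearer to Fibroblast than to Brain. The mean root mean square difference was 0.629 log2 units between SKN and Fibroblast, 0.928 between SKN and Brain and 0.929 between Fibroblast and Brain, against 0.459, 0.469 and 0.456 between arrays within Fibroblast, Brain and SKN. The ratio of the SKN distances was 0.678 (exact 2-sided permutation p = 0.1, the smallest that the 20 assignments of these 3 and 3 arrays can give, so the design cannot reach 0.05).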

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

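The fit without Fibroblast 1 and Brain 3 was chosen after the results were seen; all other alternatives were set before. The counts of calls rested on the arrays more than on the scaling: with an intensity trend, quantile normalization, median centring, array weights, the 6 arrays of 2 groups alone, genes in place of probe sets, a filter on dim probe sets or the replicate block (835, 4946 and 6026 calls), each count stayed within 1.5 times its reported value. The fit of genes gave 1078, 4178 and 4885 calls, beside 726, 3608 and 4308 genes called in the main fit. Similar counts can hide different calls. With 2 groups alone, 59.39% of the calls of SKN against Fibroblast stayed. Without variance moderation SKN against Fibroblast gave 488 calls and 291 at 2-fold or more, and a test against a 2-fold difference gave 100 calls for SKN against Fibroblast, 889 for SKN against Brain and 820 for Brain against Fibroblast, a stricter question by construction. Leaving out each array in turn gave 513 to 1095 calls for SKN against Fibroblast (410 to 675 at 2-fold or more), 3530 to 4986 for SKN against Brain (2310 to 2956) and 4876 to 6365 for Brain against Fibroblast (2684 to 3170). In the same removals the genes higher in SKN than in both others numbered 126 to 237, lower than in both 41 to 99, SKN and Brain above Fibroblast 41 to 84 and below it 79 to 178, SKN and Fibroblast above Brain 803 to 1045 and below it 970 to 1428. Probe sets higher in both SKN and Brain than in Fibroblast numbered 84 to 198, lower in both 146 to 307 and opposite 66 to 132, the ratio of distances was 0.6385 to 0.7005, and 20 to 23 list tests were called. Without Fibroblast 1 and Brain 3 the calls were 516, 3366 and 3657, the 6 gene classes in the order above 112, 41, 35, 87, 663 and 782, and the shared and opposite probe sets 85, 159 and 62. Fewer arrays give less power by construction, and how much of these falls that explains was not tested. With the lower part of the probe sets by mean left out, 146 genes were lower in SKN than in both and 137 stood above Fibroblast in SKN and Brain, and 307 probe sets were higher in both; with probe sets above the median on 3 of 9 arrays the values were 148, 139 and 311, with 206 opposite. The cause was not tested. No list test (0 of 72) passed with an estimated correlation. A second probe set of GJA1 reversed its difference, to -0.34 for SKN against Brain and 0.14 for Brain against Fibroblast, and the cause was not tested. All 40 leading gene calls with Brain (20 against SKN, 20 against Fibroblast) held in each fit that kept the probe set. The 20 leading calls of SKN against Fibroblast held but for LYVE1, PGM5, DKK2, CCN3 and TFPI2. Of the other called list members, 28 of 40 in SKN against Fibroblast, 51 of 157 in SKN against Brain and 54 of 169 in Brain against Fibroblast lost their call in at least 1 removal of an array, 20, 14 and 10 lost it with the replicate block, 30, 45 and 50 without variance moderation, 21, 29 and 15 with the arrays of 2 groups alone, and 27, 46 and 59 without Fibroblast 1 and Brain 3. Whether replicate numbers pair the samples was not settled. Deviations from group means correlated at -0.0449 to 0.145 between arrays of the same number, over 0.1 in 1 of 9 pairs (Fibroblast 1 and SKN 1). Between arrays of different number and group they correlated at -0.144 to 0.0959. With 3 arrays per group these values cannot exclude that samples share a dog. The pseudocount alternatives were not run, since the values are already logarithms. Signal over background limits what low readings show: the housekeeping gene RPL13A read about 2.2 in Fibroblast and Brain.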

Other observations

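The following were chosen after the results were seen: the genes of this paragraph and the tests of 2 further patterns, of transcripts of another culture, of 1 array or admixed glia behind the neural crest call, and of abundant Fibroblast transcripts in SKN. The transcription factors PRRX1, TBX15 and TWIST2, picked after their values were seen and in no fixed list, were lower in Brain than in SKN and Fibroblast and were not called between those. PRRX1 averaged 9.45 in both and 6.56 in Brain (SKN over Brain 2.89 ± 0.17 SE, n = 3 and 3), TBX15 7.52, 7.45 and 3.72 (3.80 ± 0.25) and TWIST2 7.45, 6.96 and 5.03 (2.42 ± 0.23). SHOX2 parted all 3 cultures, at 8.69 in Fibroblast, 5.98 in SKN and 4.01 in Brain, and was called in each comparison (SKN minus Fibroblast -2.71 ± 0.17, SKN minus Brain 1.97 ± 0.17). In Brain the glial factors SOX5 and SOX6 were higher than in SKN (-4.21 ± 0.38 and -4.25 ± 0.35 for SKN minus Brain) and than in Fibroblast (4.82 ± 0.38 and 3.69 ± 0.35). Among receptors of FGF, FGFR2 was lower in SKN than in Fibroblast (-3.01 ± 0.43) and FGFR1 higher (0.67 ± 0.10), while FGFR3 was higher in Brain than in Fibroblast (1.94 ± 0.26). These genes were not run through the alternatives.

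Of 10 housekeeping genes 0 were called by limma between SKN and Fibroblast (1 at an unadjusted p under 0.05), 2 were higher in SKN than in Brain and 3 lower in Brain than in Fibroblast, with B2M, a subunit of class I antigen presentation, lower in Brain (-1.72 ± 0.25 against Fibroblast). Tests of 2 further patterns were run and are given as values. Of 47 neural stem, astrocyte and oligodendrocyte markers, 15 (31.9%) lay below the median of all values (4.74) on all 9 arrays, against 29.1% of all genes. The cholesterol synthesis list averaged 7.021 in Fibroblast, 8.262 in Brain and 8.403 in SKN, and 5 of its 16 members were called higher in both SKN and Brain.

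Too few splits exist for a share under 0.05, since 6 arrays divide into 3 and 3 in only 10 ways. In each comparison 1 of the 10 splits, the real one, gave as many calls: 1076 against at most 3 in the others for SKN and Fibroblast, 5271 against at most 1 for SKN and Brain, and 6638 against at most 0 for Brain and Fibroblast. Every other split mixes both cultures in each group, so any difference between cultures enters the spread. Low counts there follow by construction and do not gauge chance.

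Transcripts of another culture stood out on Fibroblast 1 and Brain 3. On Fibroblast 1, 18 of 20 transcripts abundant in Brain and low on the other Fibroblast arrays lay above both of those arrays. Low readings on the other arrays were part of the choice, which favours the tested array, so 33.3% is not the chance share. Fibroblast 1 and Brain 3 were also singled out after their values were seen. Counts above both, here and below, therefore do not gauge chance. The 20 stood at a median of 4.43% of their Brain level. Such percentages, here and below, are ratios of signals and not shares of RNA or of cells. Carry-over of the Brain cultures may account for the raised readings. ENPP2 goes against it, reading 2.94 where that share predicts 6.58, and ITGB8 was not above both either (4.67 against 6.06). The 4 SKN transcripts examined (ABI3BP, AVPR1A, CXCL12 and F2RL2) all lay above both as well, at a median of 0.942% of their SKN level, and the cause was not tested. So few transcripts decide nothing. A few cells of peripheral glia in the skin culture are an open alternative, with CDH19 at 5.86 and NGFR at 7.32. The neural crest and Schwann cell list mean was 6.05 against 5.49 and 5.37. The explanations cannot be told apart. On Brain 3, 27 of 33 Fibroblast transcripts and 15 of 21 SKN transcripts, chosen by the same rule, lay above both other Brain arrays. Yet 4 of the 33 (ASPN, F3, MFAP5 and SFRP2) and 6 of the 21 (ASPN, AVPR1A, CLMP, DPT, MFAP5 and PDPN) stayed within them. For these the median share predicts at least 4-fold more. They go against carry-over at 1 share as the whole cause, as ENPP2 does on Fibroblast 1. How many such transcripts would decide was set after the results were seen, so carry-over in part stays open on both arrays. Other stromal cells stay open for Brain 3, with ACTA2 at 9.59, COL1A1 at 8.25 and POSTN at 3.05. No biological explanation is given by the design.

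The neural crest and Schwann cell list was called higher in Brain than in the other cultures at the preset correlation, with 9 members higher in Brain in each comparison, and 4 lower than in Fibroblast and 3 lower than in SKN. The call is lost with an estimated correlation (adjusted p = 0.263 with an estimated correlation, against either culture), while at the preset one no removal of 1 array ends it, the highest adjusted p being 0.03467, without Brain 3. The 9 members called higher than in Fibroblast had a median Brain level of 10.17, the 98.13th percentile of all probe sets. A small admixture of peripheral glia cannot be told apart from expression by most cells, since signals on an array that may saturate do not give a share of cells. The medium of the Brain cultures, which the labels used here do not give, was not tested.

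Of 25 fibroblast matrix members 20 were higher in SKN than in Brain, and between SKN and Fibroblast 20 were not called, 3 were higher and 2 lower. If cells like those of the Fibroblast cultures made up most of the SKN cultures, their abundant transcripts would have to stay. The 67 transcripts examined were abundant in Fibroblast and called at least 4-fold lower in Brain. Of the 67, 6 were called more than 4-fold lower in SKN (CCN3, F3, RBP4, SFRP2, STXBP6 and TFPI2). These 6 lay at 0.801% (SFRP2) to 18.4% (STXBP6) of the Fibroblast signal, which is not a share of cells. The rest were not so called, with LUM at 104%, DCN at 85% and CNN1 at 12.6%. The median log2 difference of the 67 was -0.62, but they were picked on the same Fibroblast arrays, which alone can lower it. CCN3, RBP4, SFRP2 and TFPI2 were already known as leading genes lower in SKN when this test and its threshold were set. The test thus restates calls of the same comparison. It shows that the SKN cultures differed from the Fibroblast cultures in these transcripts. It does not decide which cells made up the SKN cultures. Cells of the same lineage that changed in serum-free medium with EGF and FGF, and another stromal lineage of skin, both stay open and untested, since medium and cell type move together in this design.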
